A study of Drosophila melanogaster with 12 samples.

How the data were processed

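The data are DamID-seq profiles of Polycomb from 3 larval sources, with 2 biological replicates of Dam-Polycomb and 2 of Dam only for each, and 3 technical replicates of each brain Dam-only replicate, per the series' design text. Per the labels, methylated fragments were amplified by PCR, sheared and sequenced. The submitters' processing notes name cutadapt, Bowtie2 and HTSeq and the genome build dm3, without versions. The deposited values are log2 ratios per GATC fragment, normalized to Dam only and averaged over replicates by the authors, per the file headers and the series' design text. The log base was checked on the values: the fragments at the half-log2 steps expected for small whole read counts around the most frequent score numbered 2105 in brain, 4550 in fat body and 5127 in glia, against at most 640 at the steps of other log bases (tolerance 0.0011). The rule by which fragments were left without a score is not given in the sources used here. No read counts, single replicates or Dam-only values were analysed here, so the depth is unknown, no error between animals can be given, and no test across animals was run.

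Coordinates are those of the deposited table, in dm3 (release 5), counted from 1. The gene tables at hand describe release 6, and coordinates were not carried between builds. Regions are therefore named by position only, with no gene, exon or intron. The analysis fixed beforehand was written for genes. Its gene scores, gene lists, cell type markers, windows around transcription start sites and a check of the Polycomb gene for transgene reads were not run, and 10-kb bins took the place of genes.

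Domains were called in each profile on arms 2L, 2R, 3L, 3R, 4 and X with a hidden Markov model over scored fragments in genome order (2 states, Student t emissions with 4 degrees of freedom, expectation maximisation, Viterbi path), keeping runs of at least 5 scored fragments in the upper state. A 3-state version, whose top state was taken as domain, was added after seeing the data because the upper of 2 states held over 50% of fragments in fat body and glia. Overlap was counted over fragments scored in both tissues and set beside independent placement and 1000 circular shifts. A domain counted as shared where at least 50% of its fragments scored in the other tissue were in a domain there. Bins of 10 kb were the mean of at least 5 scored fragments, and a difference over 1 on the log2 scale was counted. The scatter of a bin mean and the reliability came from odd and even fragments of each bin with at least 3 scores in each. Every SD is a spread over fragments along the chromosome, not between animals.

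The named regions follow the rule fixed for genes before the data were examined, applied to domains and bins. It took the 10 domains with the highest mean per profile and, per pair of profiles and direction, the 10 bins with the largest difference as deposited among bins with at least 5 scored fragments that lay by at least 50% in a 2-state domain of 1 profile of the pair and not of the other, with 1 bin per domain. The longest brain domain, the bins within and beside the highest brain domain, chromosome 4 and the heterochromatic stretch were chosen after their values were seen.

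The procedures were tested on simulated scores at the real fragment positions. Domains and their overlap used scores drawn from the fitted models. Bin differences used the same bin means in both profiles plus normal scatter over fragments. The 2-state caller recovered 99.5% of simulated domain fragments in brain (121640 fragments), 96.6% in fat body (151059) and 97.8% in glia (192284). The 3-state caller recovered 99.4%, 90.4% and 97.9%. With changes between states drawn with equal probability, which put 49.1% of brain, 36.5% of fat body and 43.1% of glial fragments in domains, it recovered 99.4%, 91.8% and 98.5%. A single starting point had missed the top state there in brain and glia, so 2 starting points were used for the 3-state fit, and the later was kept where its log likelihood was over 10 higher, which did not happen in the real profiles. Independent simulated 3-state domain sets overlapped at 1.02 (brain and fat body), 1.03 (brain and glia) and 0.983 (fat body and glia) times the independent expectation. With 200 bins shifted, a shift of 3 was called in 100% of 100 bins for each pair, and a shift of 1.5 in 79.0% of 100 bins for brain and fat body, 88.0% for brain and glia and 93.0% for fat body and glia. Of unshifted bins, 4.23% of 9627, 2.01% of 10201 and 3.38% of 10568 were called in the same order of pairs. These shares cover scatter over fragments only, with no offset between profiles and no variation between libraries.

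Alternatives set beforehand were a running mean over 11 fragments, Gaussian emissions, other minimum sizes, fragments of 200 to 2000 bp, quantile normalization, centring, leaving out X, other bin filters and thresholds, and Spearman correlation. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.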

Results

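Polycomb is a chromodomain protein of the Polycomb repressive complexes, which keep many developmental regulator genes silent. Its binding was mapped by DNA adenine methyltransferase identification (DamID), in which a bacterial methyltransferase (Dam) fused to Polycomb methylates GATC sites near the places where Polycomb sits, and Dam alone gives the background of accessible chromatin. The series held 12 libraries in 6 groups of 2 biological replicates, Dam-Polycomb and Dam only from the larval central brain, the larval fat body and repo+ glia of the central brain. Larvae were Drosophila melanogaster at the wandering stage, with 20 larvae per sample for brain and glia and 10 for the fat body. The brain profile came from the uninduced form of a Dam that carries a 4-hydroxytamoxifen-dependent intein, in males. The fat body profile came from the same system after induction with 25 uM 4-hydroxytamoxifen, also in males. The glial profile came from a construct switched on by a recombinase under the control of repo, which encodes a glial transcription factor, in both sexes together. Between brain and fat body, tissue and induction of the system therefore changed together. In each comparison with glia, tissue, DamID system and sex changed together.

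The deposited values were 1 log2 ratio of Dam-Polycomb to Dam per GATC fragment and tissue, each the authors' mean over the replicates. They carry no error between animals, and the read depth behind them is unknown. Of 356504 fragments, 122591 (34.4%) had a score in brain, 152409 (42.8%) in fat body and 196103 (55.0%) in glia, and 92822 had one in all 3 profiles. Short fragments were scored least: of the 179736 fragments under 200 bp, 8.91% had a score in brain, 17.8% in fat body and 30.3% in glia. The median score was -1.24 in brain, 0.09 in fat body and -0.60 in glia. Scores are given as deposited unless the surrounding sentences name median-centred values (the score minus the median of its own profile).

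Polycomb in the central brain lay in a limited number of strongly enriched domains. The 2-state model placed 307 domains on the 6 chromosome arms, covering 13.9 Mb and 18.1% of the scored fragments, with a median length of 25.9 kb. The median score was 3.84 inside them and -1.61 outside, a gap of 5.44. In the fat body and in glia the same model divided the genome at a lower level. Its upper state held 56.1% of the scored fragments in fat body (2470 domains, 70.1 Mb) and 57.4% in glia (1948 domains, 63.4 Mb), with gaps of 2.60 and 2.43 between the medians inside and outside. A 3-state model, chosen after seeing the data, split off a top state in those tissues. The top state formed 1927 fat body domains of 30.3 Mb (27.2% of scored fragments, median score inside 2.14) and 554 glial domains of 12.9 Mb (13.2%, median score inside 2.69). In brain it gave 349 domains of 14.0 Mb, close to the extent under 2 states. Domains are named by their 2-state or 3-state origin below.

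**Figure D1:**
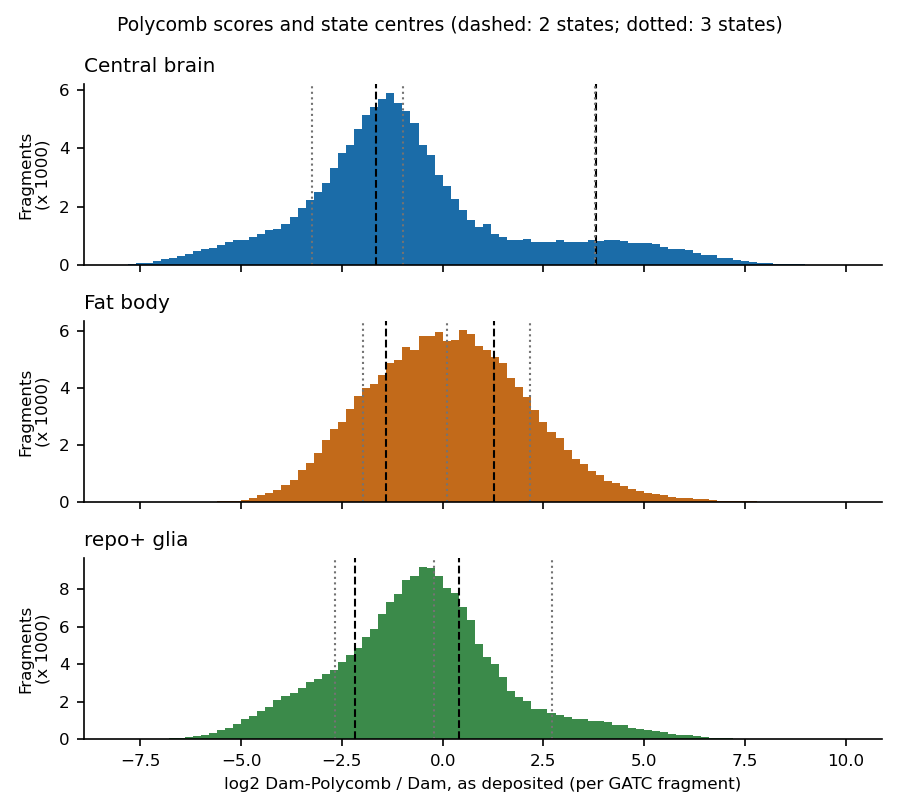
Distribution of the deposited log2 Dam-Polycomb to Dam ratio over GATC fragments of the 6 chromosome arms (x axis, bins of 0.2; y axis, fragments in units of 1000) in central brain, fat body and repo+ glia. Dashed lines mark the state centres of the 2-state model and dotted lines those of the 3-state model; the upper 2-state centre was 3.80 in brain, 1.28 in fat body and 0.40 in glia.

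The share of each chromosome arm inside brain domains (2-state) ranged from 14.0% of scored fragments on 2R to 21.2% on X among the large arms. Chromosome 4 stood apart with 44.5%, in 7 domains of together 0.292 Mb. Its fragments outside domains had a median of -4.04 in brain, against -1.50 to -1.72 on the other arms. In glia the chromosome 4 median outside domains was -2.42, against -2.03 to -2.24 elsewhere, and in fat body it was -1.58, against -1.34 to -1.49. On X, the 3-state fat body domains held 33.2% of scored fragments, more than on any other arm (21.3% on chromosome 4 to 27.1% on 3L), whereas in glia X (12.9%) lay within the range of the others (11.6% to 16.6%). With 2 states X held the highest share in both profiles, by a wide margin only in glia. The glial share was 66.1% on X against 40.9% to 57.2% elsewhere, and the fat body share 58.8% on X against 41.7% to 57.95%.

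The 10 brain domains with the highest mean score were spread over 2L, 2R, 3L, 3R and X. The highest lay on 3R from 12482603 to 12814490 (dm3), 332 kb long, with a mean of 6.47 (SD along the domain 1.39, 415 fragments) in brain, 2.90 in fat body and 4.79 in glia. The longest brain domain, also on 3R, ran 404 kb from 2487040 to 2891255 and had means of 5.12 in brain, 3.19 in fat body and 3.70 in glia. Several top brain domains were high in all 3 profiles. The domain on 2L from 20760746 to 20787083 had means of 6.36 in brain, 4.71 in fat body and 4.51 in glia. That on 3R from 20901392 to 20922476 had 6.21, 5.11 and 4.40, and that on 2R from 7348566 to 7466198 had 6.07, 4.04 and 3.87, in the same order of tissues. Other top brain domains were far lower elsewhere. On 3R from 163104 to 184928 the mean was 6.22 in brain, 1.30 in fat body and 0.74 in glia, which is 7.46, 1.20 and 1.34 above the respective profile medians. On X from 4529800 to 4541371 it was 6.11 in brain, 1.75 in fat body and 0.86 in glia.

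The top-ranked domain of fat body and glia (2-state) was the same stretch of X, from 8500451 to 8569698, with means of 5.18 in fat body (SD along the domain 1.87), 4.71 in glia (1.35) and 5.28 in brain (1.52). The fat body mean rested on 42 scored fragments, against 128 in glia and 100 in brain: in its part from 8500001 to 8550000, only 29 of the 77 fragments scored in brain and glia had a fat body score. Another X domain from 17649118 to 17715344, ranked 4 in fat body, had a mean of 4.74 there, 5.47 in brain and 4.66 in glia. The second-ranked fat body domain lay near the median of the other profiles. On 3L from 5584435 to 5594858 the mean was 5.02 in fat body, -1.14 in brain (9 fragments) and -0.53 in glia (30 fragments). The latter values lay 0.10 and 0.07 above their profile medians. Among the glial top 10, the domain on 3R from 11809093 to 11869565 had a mean of 4.10 in glia and 5.28 in brain but 1.29 in fat body. The glial domain on 3L from 8992944 to 9040894 was higher in fat body (4.78) and glia (4.34) than in brain (3.16) as deposited, and 4.69, 4.94 and 4.40 above the medians.

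**Figure D2:**
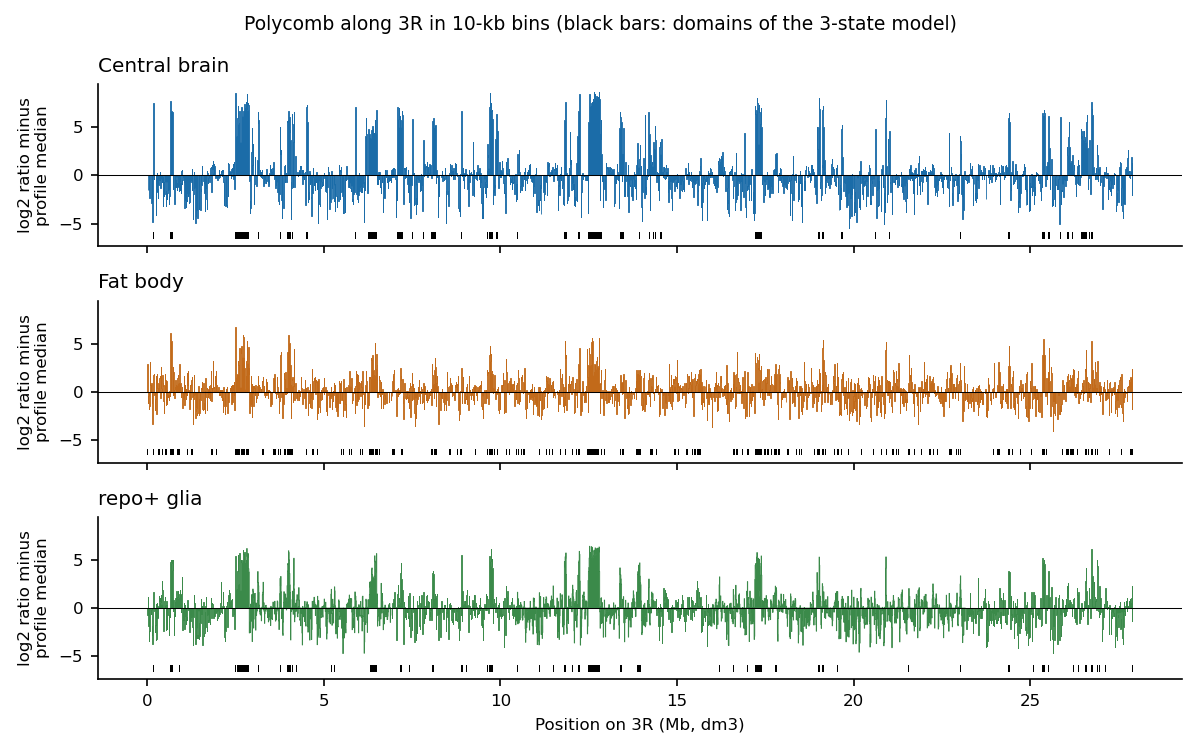
Median-centred log2 Dam-Polycomb to Dam ratio in 10-kb bins along chromosome arm 3R (x axis, Mb in dm3; y axis, log2) for central brain, fat body and repo+ glia, with black bars for 3-state domains. The tallest broad block in brain is the domain from 12482603 to 12814490, with a centred mean of 7.70 in brain, 5.39 in glia and 2.81 in fat body.

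Within the highest brain domain on 3R, the 3 profiles had different shapes. Brain stayed high in every full 10-kb bin from 12490001 to 12810000, with centred means from 5.51 to 8.67. Glia followed at 3.80 to 6.41 over the same bins. The fat body was at 5.15 to 5.54 in the 4 bins from 12570001 to 12610000, at 1.67 in the bin from 12650001, at 1.10 in the bin from 12750001 and at 5.54 in the bin from 12790001. Outside the domain, the bin from 12450001 to 12460000 had a centred mean of 4.42 in fat body, -0.44 in brain and -0.74 in glia. Between that bin and the domain, the bin from 12470001 was low in all 3 profiles, at -2.06 in fat body, -3.89 in brain and -1.88 in glia. The odd-even scatter of a bin mean was 0.32 in brain, 0.33 in fat body and 0.27 in glia, so these steps were many times larger than the scatter along the chromosome. On the other side, the bin from 12850001 to 12860000 was at 5.80 in brain, 2.21 in fat body and 1.07 in glia.

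**Figure D3:**
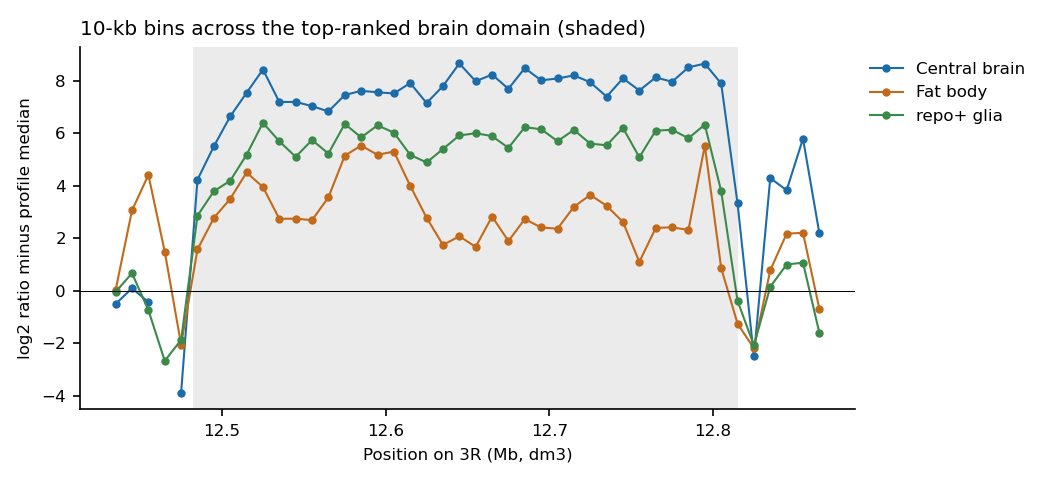
Median-centred log2 ratio in 10-kb bins (points) across the brain domain on 3R from 12482603 to 12814490 (shaded) and 5 bins on either side, in central brain, fat body and repo+ glia (x axis, Mb in dm3; y axis, log2). Fat body reached 5.54 in the bin from 12790001 and 1.10 in the bin from 12750001, while brain was at 8.67 and 7.64 there.

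Whether the tissues share Polycomb domains was asked next. Of the 289 brain domains (2-state) with at least 5 scored fragments in both other profiles, 248 lay by at least 50% in domains of both, and 9 in neither. Since those fat body and glial domains covered most of the genome, the 3-state domains gave a stricter view. Of 322 such brain domains, 191 lay in fat body domains, 164 in glial domains, 137 in both and 104 in neither. Of 1586 fat body domains (3-state), 1222 lay in neither other tissue, and of 442 glial domains 312 lay in fat body domains, 194 in brain domains and 101 in neither. With 2 states 544 of 2122 fat body domains and 240 of 1731 glial domains lay in neither other tissue. Over fragments scored in both tissues of a pair, brain and glia (3-state) shared 13360 domain fragments, 3.97 times the 3363 of independent placement. The ratio was 2.02 for brain and fat body (9874 against 4896) and 2.67 for fat body and glia (11588 against 4343). These ratios, like the counts in neither tissue, depend on how much each domain set covers, so they do not rank the pairs. Of brain domain fragments 66.5% lay in fat body domains and 63.6% in glial domains, sets that held 33.0% and 16.0% of the fragments compared. Of glial domain fragments 73.4% lay in brain domains and 77.5% in fat body domains. With 2 states the ratios were 1.34 for brain and fat body, 1.47 for brain and glia and 1.40 for fat body and glia. None of 1000 circular shifts of a domain set along the genome gave an overlap as large, for any pair under either model, which describes these profiles and not a spread between animals.

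Edges of corresponding domains mostly lay over 1 kb apart. Of 200 pairs of brain and glial domains (3-state) that were each other's best overlap, 122 of 400 edges (30.5%) lay within 1 kb of each other and 68 fell on the same GATC site, with a median distance of 3.07 kb. For brain and fat body 121 of 498 edges (24.3%) lay within 1 kb (median distance 4.21 kb), and for fat body and glia 226 of 752 (30.1%, median 3.29 kb). No chance value was computed for these distances. An edge can fall only at the end of a scored fragment, and the scored fragments differ between profiles, so missing scores alone can move it. Brain domains (2-state) differed widely in level outside the brain. Their centred median was 1.46 in fat body (quartiles 0.59 and 2.61, 289 domains) and 1.96 in glia (quartiles 0.55 and 3.66, 305 domains). In fat body 52 of them lay over 3 above the profile median and 34 lay below it. In glia 112 lay over 3 above the median and 39 below it. Across brain domains, which are not independent replicates, the brain level correlated with the glial level (Pearson r 0.472) and with the fat body level (0.337).

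The genome-wide profiles were more alike between brain and glia, and between fat body and glia, than between brain and fat body. Over single fragments Pearson r was 0.665 for brain and glia, 0.666 for fat body and glia and 0.515 for brain and fat body, with 95% intervals over 1-Mb blocks of 0.631 to 0.694, 0.650 to 0.681 and 0.485 to 0.544. Over 10-kb bins r was 0.740, 0.767 and 0.604 in the same order, and 0.756, 0.796 and 0.624 after division by the odd-even reliability of the bins. Fragments and bins are not independent replicates, and no p-value is given for them.

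**Figure D4:**
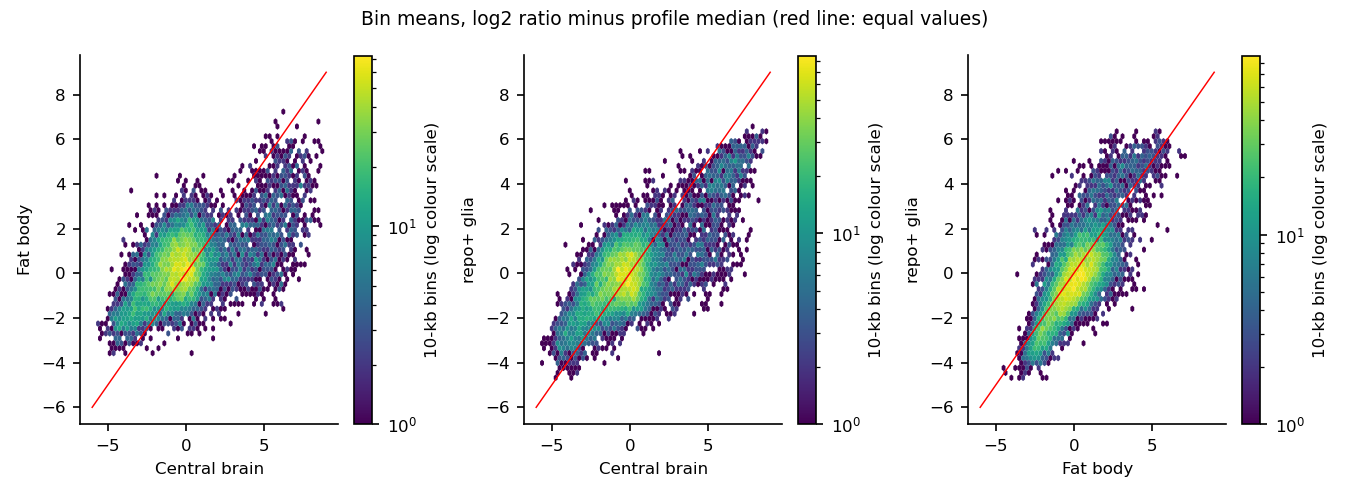
Median-centred log2 ratios of 10-kb bins for each pair of profiles (both axes log2, colour the number of bins on a log scale, red line equal values). Pearson r was 0.604 for brain and fat body, 0.740 for brain and glia and 0.767 for fat body and glia, and many bins high in brain lie near 0 in fat body or glia.

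Brain and fat body differed at loci that carried Polycomb in brain alone, or in brain and glia, among these profiles, and at others that were higher in fat body. On 3R, the bin from 14090001 to 14100000 had a score of 5.04 in brain (SD over fragments 2.14, 20 fragments), -1.40 in fat body (1.72, 16 fragments) and -1.39 in glia (1.99, 16 fragments). The bin on X from 500001 to 510000 had 6.06 in brain, -0.24 in fat body and -0.68 in glia, and the bin on 2R from 9420001 to 9430000 had 5.02, -0.63 and -0.68. By contrast, the bins on 3R from 11820001 (5.01 in brain, -1.32 in fat body) and from 19030001 (5.62 and -0.05) were also high in glia, at 3.68 and 3.85. In the other direction, the largest gap was on X from 21250001 to 21260000, at 3.79 in fat body (25 fragments), -4.62 in brain (7 fragments) and -2.19 in glia (26 fragments). The bin on 2L from 1670001 had 4.53 in fat body, -3.14 in brain and 1.83 in glia. Of the 10 bins named for fat body over brain, 7 were on X, and 8 had centred fat body means under 3.5, so that much of their gap came from brain values of -3.10 or lower. Those brain values rested on few scored fragments, 5 to 11 per bin. The 10 bins named for brain over fat body differed by 5.49 to 6.44, and those for fat body over brain by 6.36 to 8.41. After centring these ranges were 6.82 to 7.77 and 5.03 to 7.08, so the larger differences were those of fat body over brain as deposited and those of brain over fat body relative to the medians.

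Of 9827 bins compared, 958 were over 1 higher in brain and 6927 over 1 higher in fat body as deposited. The median difference over bins was -1.92, while centring on the fragment medians removed 1.328, so the balance of higher and lower bins depends on where the profiles are centred. After centring, 1884 bins were higher in brain and 3930 in fat body, which moved the share higher in brain from 12.2% to 32.4%. After quantile normalization the counts were 1362 and 4268, a share of 24.2%.

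Brain and glia differed at loci that were high in the whole central brain and near or below the glial median. The bin on X from 500001 led this direction, 6.74 higher in brain than in glia. On X from 12500001 to 12510000 the score was 4.60 in brain (SD over fragments 4.91, 14 fragments) and -1.94 in glia. The brain domain that starts in this bin, from 12505366 to 12523370, had 5.94 in brain and 0.29 in glia, the latter 0.88 above the glial median. In the bin on 3R from 25850001 the score was 4.79 in brain and -1.35 in glia, and on 3L from 13380001 it was 4.56 and -1.55. A chromosome 4 bin, from 100001 to 110000, had 3.81 in brain, -2.08 in glia and -1.71 in fat body. The bins named for glia over brain had lower tops, which the naming rule itself allows. The lowest mean of a 2-state domain was -0.79 in glia but 1.24 in brain. Part of the gap in these bins came from low brain values, which rested on 5 to 14 scored fragments per bin. On X from 14990001, for example, the score was 0.60 in glia and -5.26 in brain (5 fragments). On 3R from 15560001 to 15570000, inside a glial domain (2-state) of 183 kb, the score was 2.25 in glia, 1.41 in fat body and -3.72 in brain. On 2R the bin from 13680001 had 2.52 in glia and -2.85 in brain, and the bin from 14620001 had 3.43 in glia, 2.22 in fat body and -1.45 in brain. All 10 bins named for glia over brain had centred glial means of 0.23 to 4.03, and 9 of them had fat body means above the fat body median.

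Of 10401 bins compared between brain and glia, 1379 were over 1 higher in brain and 4779 over 1 higher in glia as deposited. After centring, the counts were 2340 and 2930, and the share higher in brain moved from 22.4% to 44.4%. Over 2 apart, 637 bins were higher in brain and 2054 in glia as deposited, but 1042 and 867 after centring, so the direction of the imbalance turned. Quantile normalization gave 1565 and 3492 bins over 1 apart, a share of 31.0%.

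Fat body and glia differed at loci of either tissue. The bin on 3R from 12450001, near the highest brain domain but apart from it, had 4.51 in fat body, -1.34 in glia and -1.67 in brain. Other fat body loci were also high in brain. On 3L the bin from 1900001 had 4.02 in fat body, 3.47 in brain and -1.20 in glia, and the bin from 7490001 had 3.89 in fat body, 3.31 in brain and a centred glial mean of -0.40. The largest glial excess was at the bins already named on 3R, from 11820001 (3.68 in glia, -1.32 in fat body) and from 19030001, and at a bin on 2L from 18860001 with 3.89 in glia, 4.31 in brain and -0.92 in fat body. Loci higher in glia than in both other profiles included 3L from 5970001, at 2.20 in glia, -1.43 in fat body and -1.35 in brain, and 2R from 11540001, at 3.10, -0.52 and -1.17 in that order.

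Of 10768 bins compared, 5757 were over 1 higher in fat body and 548 over 1 higher in glia as deposited. After centring the counts were 2771 and 1243, and the share higher in fat body moved from 91.3% to 69.0%. After quantile normalization they were 2827 and 1432, a share of 66.4%. Differences between profiles repeated between odd and even fragments of the same bins, with Pearson r of 0.905 for brain and fat body, 0.894 for brain and glia and 0.815 for fat body and glia. That repeat covers counting scatter along the chromosome and not variation between animals.

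**Figure D5:**
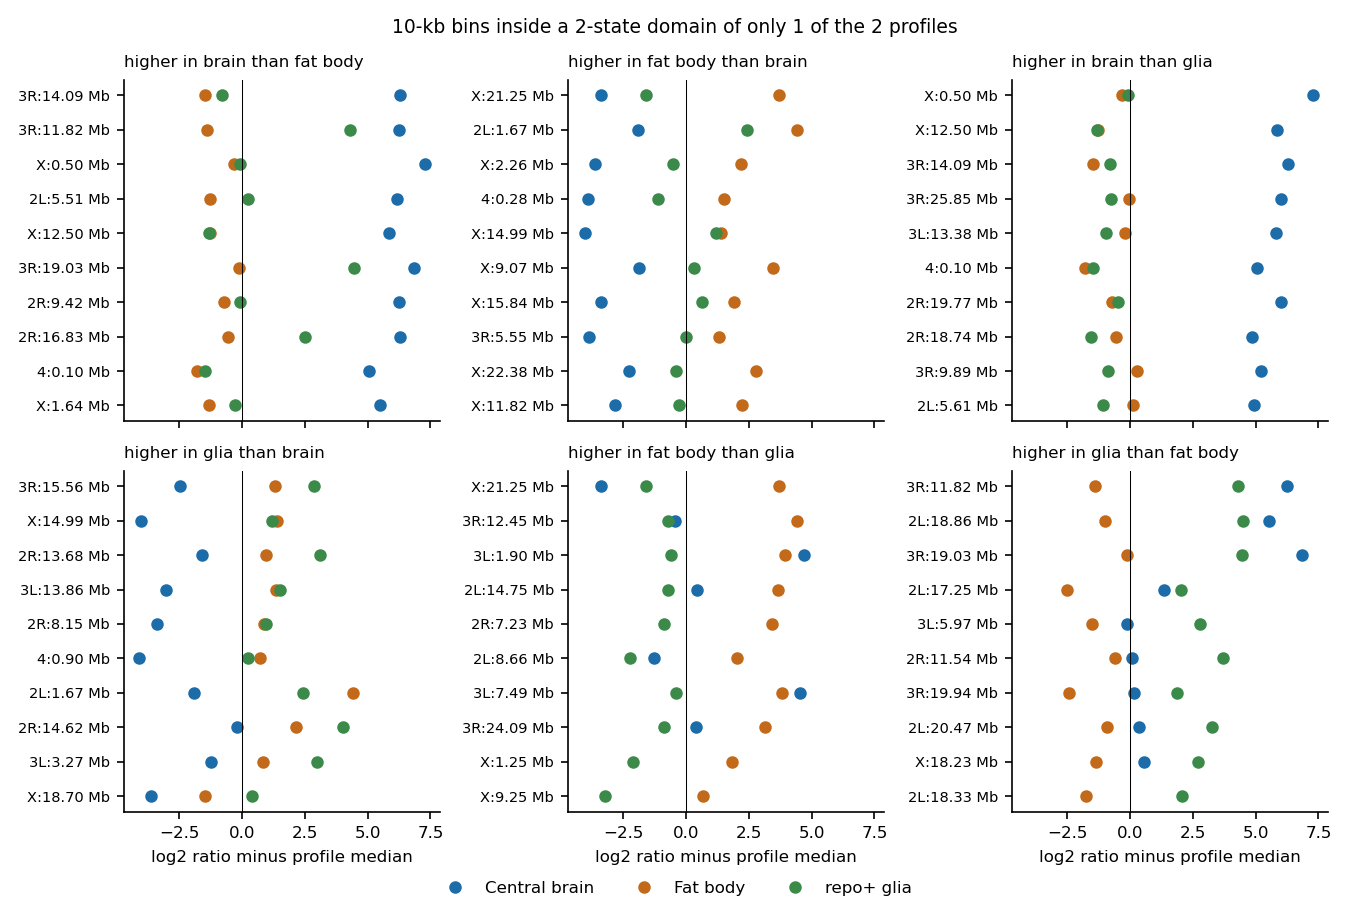
Median-centred log2 ratio (x axis) in central brain, fat body and repo+ glia for the 10 bins of 10 kb with the largest difference in each direction of each pair, among bins inside a 2-state domain of 1 profile of the pair and outside those of the other (y axis, arm and bin start in Mb, dm3). Centred differences ranged from 3.80 to 7.77, and several bins higher in brain than fat body, such as 3R from 11820001, were also high in glia.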

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

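The 3-state model, the running mean on centred scores and the bins limited to fragments of 200 to 2000 bp were chosen after seeing the data. For brain domains, the number and the fragments inside them stayed within 1.5 times under every alternative except the running mean on centred scores, which gave 700 domains. The extent of fat body and glial domains depended on the caller. Fat body domain fragments numbered 41005 with the running mean, 41056 with 3 states and 38047 with the running mean on centred scores. Glial domains numbered 734 with the running mean, 1246 after quantile normalization and 554 with 3 states, and their fragments 26986, 56742 and 25467, and 42909 with the running mean on centred scores. The percent of brain domain fragments inside fat body domains was 90.2 in the report's 2-state setting, 68.0 with the running mean, 92.6 with fragments of 200 to 2000 bp, 85.9 after quantile normalization and 66.5 with 3 states. By domain it was 90.7 with at least 50% covered and 96.5 with any overlap. In the same order the percent of brain domain fragments inside glial domains was 93.2, 65.8, 94.6, 77.7, 63.6, 91.5 and 95.1, and of fat body domain fragments inside glial domains 75.1, 31.0, 80.1, 42.4, 28.9, 69.0 and 77.6. Observed overlap stayed above independent placement in all of these that count fragments, by 1.32 to 3.97 times. With at least 10 scored fragments per bin, 580 bins were higher in brain and 2942 in fat body, 2328 higher in glia than brain, and 321 higher in glia than fat body, counts that fell mostly because fewer bins were compared (4371 of 9827, 5983 of 10401 and 7339 of 10768). The balance moved as well. The share higher in brain rose from 12.2% to 16.5% against fat body and from 22.4% to 31.9% against glia, and the share higher in fat body than glia went from 91.3% to 92.8%. Quantile normalization gave 1362 bins higher in brain and 4268 in fat body, and 2827 higher in fat body and 1432 in glia. Centring gave 1884 and 3930 for brain and fat body, 2340 and 2930 for brain and glia, and 2771 and 1243 for fat body and glia. A threshold of 2 left 573 bins higher in brain than fat body, 637 and 2054 for brain and glia, and 1683 and 153 for fat body and glia, as a stricter threshold must. Spearman correlations over fragments were 0.446 for brain and fat body, 0.546 for brain and glia and 0.635 for fat body and glia. Over 10-kb bins Pearson r was 0.604, 0.740 and 0.767, and with fragments of 200 to 2000 bp it was 0.690 for fat body and glia. Other than for the threshold and the fewer bins, the cause was not tested. The 60 named entries, in which some bins recur, kept their direction and stayed over 2 apart wherever they were recomputed. This held for 60 of 60 with the median of fragment scores, 60 of 60 after quantile normalization and 56 of 56 with fragments of 200 to 2000 bp. Little support comes from this, since the bins were picked from these same scores for differences of 3.11 or more. Centring was no test of these bins, since it shifts a pair by 1 constant smaller than the differences. The filter of at least 10 scored fragments was no test either. It kept 37 of the 60 entries with their means unchanged and removed the others, which had fewer scored fragments. No paired analysis was possible because the deposited columns carry 1 mean per tissue and no replicate numbers. For the same reason leaving out each replicate and tests on counts or replicate scores were not run, and the alternatives for genes and gene lists were not run because genes were not placed on this build. The unknown depth limits what a missing score can tell.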

Other observations

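All tests in this part were chosen after the result was seen, except those of the X chromosome shift, of the bins that quantile normalization took below the threshold, and of fragments under 200 bp and over 2000 bp against those of 200 to 2000 bp. Outside the 6 arms used above, 1 stretch of heterochromatin carried a Polycomb signal in brain as high as the euchromatic brain domains. On 3LHet, 27 brain fragments scored above 3.78, the centre of the top brain state, and all of them lay in 24.2 kb from 200388 to 224603. The medians over this stretch were 4.50 in brain (40 scored fragments), 3.32 in fat body (16) and 2.16 in glia (42), against medians of -3.04, -0.97 and -1.59 for the whole of 3LHet. The glial value lay below the median of 2.69 inside glial domains (3-state). No fragment of the other heterochromatic arms in brain reached that level. Within the stretch the tissues diverged: the fragment from 209271 to 209639 scored 5.91 in brain, 6.05 in fat body and 3.21 in glia, while that from 223676 to 224603 scored 3.81 in brain and -0.62 in glia.

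Long fragments had a different balance between the tissues. Over fragments of 200 to 2000 bp the fat body minus glia difference had a median of 1.20, and over fragments longer than 2000 bp it was -0.33. The brain minus fat body difference was -1.96 and -0.28 in these classes, and the brain minus glia difference -0.74 and -0.57.

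Fat body scores were missing in long stretches that were well scored in both other profiles. Of 113744 fragments scored in brain and glia, 81.2% had a fat body score, but on 2L from 17050001 to 17100000 only 7 of 47 did, against 39.5 expected from their lengths, and on X from 20450001 to 20500000 only 14 of 43. Random loss at the rate of each length class did not give such clusters: 206 of 2283 bins of 50 kb fell over 4 binomial SDs short, against at most 3 in 1000 simulations. The simulations dropped fragments independently of their read counts, so they cannot exclude fewer reads in the fat body libraries. A single X in males is not enough, since 64.1% of these bins were autosomal, although X bins were hit more often (17.8% against 7.07%). Of the 206 bins 132 had a neighbour that was also short, against at most 70 in 1000 shuffles, and on 2L, 3L and X runs of 5 bins (250 kb) occurred. The neighbours describe the pattern again and support no explanation over another. Fewer reads, lower DNA copy number of whole stretches in the polyploid fat body and lower access of Dam to them all stay open, since no read counts were analysed here. Without adjustment for fragment length, scores were missing more often in brain domains (2-state). There 14722 of 22021 brain fragments had a fat body score, against 94331 of 121640 overall. The overlap of brain and fat body therefore rests on a part of the brain domain fragments. The short bins had a median brain mean of -0.815, against -1.57 over all bins compared, and a glial one of -0.64 against -0.73.

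Several technical sources could contribute to the differences between brain and glia. A difference of scale alone between the DamID systems could not be settled. Quantile normalization left 48.6% of bins over 1 apart and took 30.2% of the bins past the threshold below it, so scale may account for part. It ranked each profile over its own scored fragments, 121640 in brain and 192284 in glia, so an equal order need not bring bins together. Over 10-kb bins the order was only partly shared (Spearman rho 0.583), but variation between libraries, which was not measured, also lowers that value. Sex acting through X alone is argued against by the autosomes, where 50.3% of bins differed by over 1 after centring, against 52.3% on X, and the X fragments departed from autosomal ones by 0.0795 in the median difference (95% interval over 1-Mb blocks -0.20 to 0.34), too wide to settle a small shift. Fragment length alone is argued against by the correlation of 0.893 over 2346 bins between differences in fragments of 200 to 500 bp and of over 500 up to 2000 bp, although fragments under 200 bp departed by 0.53 from those of 200 to 2000 bp, and those over 2000 bp by 0.17. A difference between the whole brain and its glia, the change of DamID system and sex acting beyond X stay open and cannot be told apart in this design.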
